A study of Mus musculus with 4 samples.

How the data were processed

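CTCF ChIP-seq was carried out on heart tissue from 2 pools of female B6CASTF1/J mice, each sequenced as 2 technical libraries. Per the labels, pool G is biological replicate 2 and pool H biological replicate 1. The 8 deposited peak lists were analysed: 4 thresholded by IDR and 4 ranked lists of all candidate peaks. Which list was made from which pool was taken from the readme texts deposited with the samples. The peak lists are on mm10, per the labels. The aligner and the peak caller are not given in the sources used here. A control alignment used by the authors was not analysed here.

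Per those readme texts, the authors made a ranked and a thresholded list from each pool and 2 of each from both pools, and a further file, whose content is not given in the sources used here, entered the thresholded lists. The authors deposited the caller's signal for each peak as a score without a stated unit. A further deposited score is the IDR scaled so that 540 stands for 0.05 and 830 for 0.01; the minimum in every thresholded list was 540. The ranked lists also hold the −log10 of the global IDR, as deposited by the authors, and the signals of the matched pair of calls. In the ranked list that was matched between pools, 71.7% of the first members were identical in position and signal to a pool H record and 77.3% of the second members to a pool G record, with none crosswise. Each thresholded list held the ranked peaks with a scaled IDR of at least 540, apart from a few peaks described with the results held for a closer look. The signal grows with depth, so it is not compared between lists as a level, and the pool G and pool H values of a peak are given side by side for description. Read depth is unknown, and the intervals given cover counting error over peaks or genes only.

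The conservative list was the main list, and its 54309 records have 53212 distinct intervals, since 1 interval can hold several summits. The genome was GRCm38.p6, whose chromosome lengths held all peaks, with soft-masked sequence as deposited in that assembly, and the annotation was GENCODE M21. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlap meant at least 1 shared base. Feature classes were assigned to summits in the order promoter (within 1 kb of any TSS), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and were set against 100 draws of uniform positions outside runs of N on the same chromosomes.

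The motif matrix was learned on odd autosomes from exact matches to the seed CCASNAGRKGGC within 100 bp of the summit, with 4 bases added on either side and 3 rounds of refitting. A motif was called above the score reached by 1% of training windows 1 kb from the summit. It was tested on even autosomes and X with a McNemar exact test. This is the analysis fixed before the data were examined, together with the seed at up to 1 mismatch as its alternative. The number of flanking bases and of rounds was not fixed in that plan and was set when the learner was written. After its 15.7% share and its consensus on a soft-masked word had been seen, 9 further versions of the matrix or seed were tried, which gave 21.3 to 46.9%. The one learned outside soft-masked sequence gave the highest of these shares and is reported because it leaves out the soft-masked copies of that word; the planned matrix remains the main result. Its threshold was reset on the same windows with soft-masked bases included.

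Orientation was tested by permuting strands within chromosomes 10000 times. Signal differences used 100000 resamples, and 10000 for the alternatives. Gene lists, named genes and tests were fixed at the same time. Orientation p-values were adjusted over 12 tests per matrix and feature p-values over 16; these adjustments were added after the results had been seen and decide whether an alternative kept a call. Genes matched by a prefix were limited to protein-coding genes. As first coded, the prefix match missed part of the gamma protocadherins, which the rule includes; this was corrected after the results had been seen, and the earlier values were 32 of 39 genes with an adjusted p of 1.39e-08. The rule for named genes took, from each list, up to 3 members with the strongest promoter peak and up to 2 without one, the 10 strongest peaks, and 12 fixed loci within 10 kb of a TSS. The text gives values for part of these; the result for 1 named gene is withheld and not reported here. The occupancy of single words of the core, the protocadherin subclusters and the count of peaks in gene bodies were added after seeing the data.

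Scripts were tested on simulated data. A core word planted in windows around random positions was found in 100.0% of 3224 windows, with a hit in 1.09% of 4776 windows without one; all 32 words were planted equally often, so this did not test for a word carried by repeats. Moving 10% of 10000 random positions to a TSS gave a promoter share of 15.9% where 15.8% was planted. Random gene sets gave 0 calls in 380 list tests, and a marked list was called in 20 of 20 simulations. Random strands gave p under 0.05 in 2 of 20 simulations. A planted log2 shift of -0.25 was recovered as -0.25.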

Results

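Binding of CTCF was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in heart tissue of adult female mice, 2 months old. CTCF is a zinc-finger protein that holds chromatin loops in place together with the ring-shaped cohesin complex. The animals were B6CASTF1/J, a first-generation cross of a C57BL/6J and a CAST/EiJ parent. Each of 2 pools, G and H, joined 2 heart biosamples and was sequenced as 2 technical libraries, so that 4 libraries and 2 biological replicates underlie the data. No other tissue or treatment was part of the series. The design therefore asks where CTCF is bound in the heart and how far the pools agree. The 8 peak lists hold no read totals, so the depth of each library is unknown. All coordinates are on mm10, and the signal of a peak is the peak caller's value as deposited by the authors, which is compared only within a list unless said otherwise.

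CTCF occupied 54309 sites in the conservative list, which the authors made from both pools at an irreproducible discovery rate (IDR) of 0.05. The peaks had a median width of 367 bp, merged into 52823 regions and covered 18.6 Mb, or 0.683% of chromosomes 1 to 19, X and Y. A second list of both pools held 62345 peaks. Pool G alone gave 54658 peaks and pool H alone 50577. At an IDR of 0.01, 51802 peaks of the conservative list were left.

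The pools shared most of their sites, and their signals were correlated. Of the conservative peaks, 91.4% (95% exact binomial interval 91.2 to 91.6) overlapped a peak of the pool G list by at least 1 bp and 89.6% (89.3 to 89.8) one of the pool H list. IDR had selected the conservative peaks for agreement between the pools, so these 2 shares are not independent evidence of it. Between the pools, 88.5% of pool G peaks overlapped a pool H peak and 91.9% of pool H peaks a pool G peak. The Jaccard index of covered bases was 0.641. Across the 166014 ranked peaks matched between pools, the signals correlated with a Spearman rho of 0.882 and a Pearson r of 0.946 on log2 values. For the 111680 of them under the IDR threshold, which itself depends on agreement, rho was 0.640 and r 0.684. Peaks are not independent replicates, and no test across the 2 pools was made. Signals of both pools lay within 100 bp of 53538 conservative summits, of peaks that IDR had selected for agreement between the pools. The pool G value was 1.23 times the pool H value at the median, and 216 peaks, 0.403%, departed from that ratio by more than 2-fold.

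**Figure D1:**
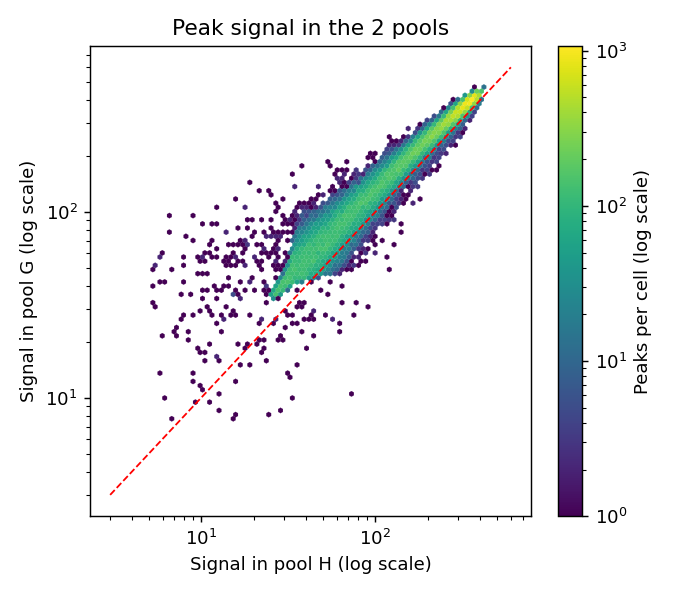
Signal of each conservative peak in pool H (x axis) and pool G (y axis), both on log scales and without a stated unit, for 53538 peaks; colour gives the number of peaks per cell and the dashed line equality. Most peaks lie slightly above the line, at a median ratio of 1.23.

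Promoters carried far more CTCF peaks than their length would give, although a smaller share of them held the CTCF core than elsewhere (values below). Within 1 kb of an annotated transcription start site (TSS) lay 11072 summits, 20.4% (20.0 to 20.7), against 6.34% ± 0.094 (SD over 100 draws) of positions drawn on the same chromosomes, a 3.21-fold excess. Intergenic sequence was depleted, with 33.6% of summits, 0.672 times the share drawn. Introns held the most summits, 41.1%, close to the 40.3% drawn. Coding exons held 1.31% against 0.897%, 3' UTRs 1.93% against 1.38%, 5' UTRs outside promoters 0.0589% against 0.0342% and other exons 1.57% against 1.08%. Soft-masked repeats held 21.8% of summits against 33.7% drawn. In the direction given, each of these one-sided permutation tests had p = 0.0099, the smallest that 100 draws can give, and 0.0198 after Benjamini-Hochberg adjustment over 16 tests. The 5' UTR excess, of 32 summits, did not pass with the pool G list (0.0494% against 0.0356%, permutation test, adjusted p = 0.178) or with peaks at or above the median signal (adjusted p = 0.0990). The intron excess was small and turned into a depletion (39.1% against 40.3%) among peaks with a signal at or above the median. The drawn positions took no account of where reads can be placed uniquely, and no mappability track was at hand. The depletion of soft-masked repeats therefore cannot be told apart from loss of reads in repeats.

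Promoter peaks had a lower median signal than distal ones across the list, but not among peaks that carry the CTCF core (values in the next paragraph). The median signal was 251 at 11072 promoter peaks and 297 at 43237 others, a difference of -0.24 on the log2 scale. The two-sided permutation test gave p = 1e-05, the smallest that 100000 resamples can give; it describes peaks of this list, which are not replicates.

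Most CTCF peaks carried the known CTCF core close to the summit. On the even autosomes and X, the fixed 12-base core CCASNAGRKGGC with at most 1 mismatch occurred within 100 bp of the summit in 16720 of 25440 peaks, 65.7% (65.1 to 66.3), against 5.48% of paired windows 1 kb away. In 15766 pairs the core was at the summit alone and in 441 in the paired window alone (McNemar exact test, log10 of p = -4001). Where present, the core's centre lay a median of 7.5 bp from the summit. The share rose from 46.4% in the weakest decile of peaks by signal to 81.6% in the strongest. At promoters the core was found in 42.6% of peaks (41.2 to 44.0) and elsewhere in 71.3% (70.6 to 71.9), an odds ratio of 0.300 (Fisher exact test, two-sided, p = 9.36e-302). Among peaks with the core the median signal was 394 at promoters and 350 elsewhere, and among peaks without it 184 and 198. With the matrix learned outside soft-masked sequence, described below, these medians were 527 and 426 with the motif and 195 and 198 without; none of these differences was tested.

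The planned matrix, learned from these data, found a motif in fewer peaks. Its consensus, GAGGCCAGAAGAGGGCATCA, holds a word of the core that lies almost wholly in soft-masked sequence. It marked 3985 of 25440 peaks, 15.7% (15.2 to 16.1), against 0.861% of paired windows. Among discordant pairs 3933 had the motif at the summit alone and 167 in the paired window alone (McNemar exact test, log10 of p = -932). This share fell with signal, from 21.1% in the weakest decile and 24.5% in the next to 4.22% in the strongest. A matrix learned in the same way outside soft-masked sequence, chosen after seeing the data, had the consensus TTGGCCACCAGGGGGCACTA. It marked 46.9% of peaks (46.3 to 47.5) against 0.790%, and its share rose with signal to 72.8% in the strongest decile.

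**Figure D2:**
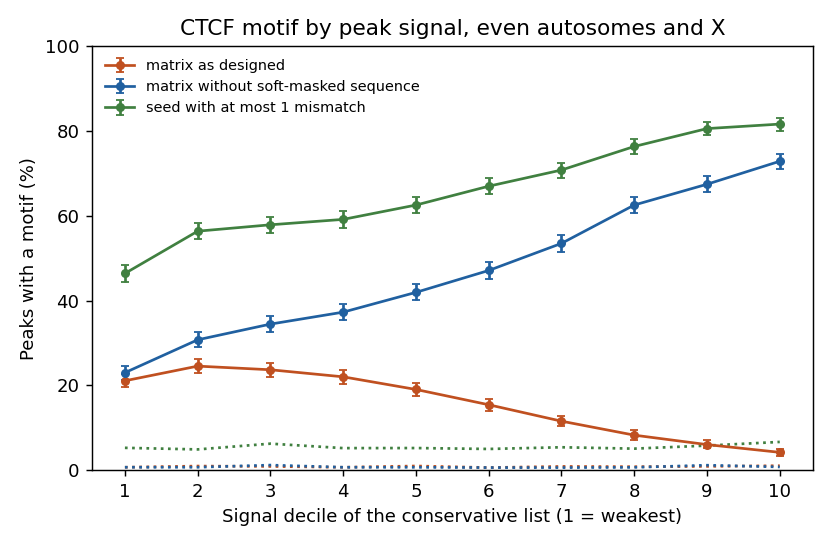
Share of conservative peaks with a motif (y axis, percent) by signal decile (x axis, 1 the weakest) on even autosomes and X, for the matrix as planned, the matrix learned outside soft-masked sequence, which was added after seeing the data, and the core with at most 1 mismatch. Bars are 95% exact binomial intervals and dotted lines the paired windows 1 kb away; the planned matrix falls to 4.22% in the strongest decile while the core rises to 81.6%.

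Word by word, CTCF occupied copies of the core very unevenly. The 32 exact words of the core had 76898 copies on the chromosomes, of which 18106, 23.5%, lay within 100 bp of a conservative summit. A single word, CCAGAAGAGGGC, made up 50566 copies, 99.6% of them soft-masked. It was occupied at 6804 copies, 13.5% (13.2 to 13.8), with a median peak signal of 163. The other 31 words were occupied at 42.9% of 26332 copies (42.3 to 43.5), with a median signal of 539. Outside soft-masked sequence these other words were occupied at 52.7% of copies. Among these 31 words the share ran from 5.83% of 857 copies of CCAGGAGATGGC to 86.1% of 467 copies of CCACTAGGGGGC.

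With the planned matrix, no departure of neighbouring motifs from random orientation passed adjustment in the conservative list, while some did in other lists. That matrix marked 15.7% of peaks and the core with at most 1 mismatch 65.7%, so its consecutive sites pass over most core-bearing peaks. Its consensus also holds a soft-masked word, so its pairs cannot decide the orientation of CTCF motifs in general. Of 8927 pairs of consecutive sites 24.6% (23.7 to 25.5) were convergent, that is, pointed towards each other, against 25.0% with strands permuted within chromosomes (two-sided permutation test, p = 0.148, 0.356 after Benjamini-Hochberg adjustment over 12 tests). Over all distances, convergent pairs must alternate along a chromosome with divergent pairs, which point apart, so both shares are nearly equal. Tests over all distances therefore set tandem pairs against all others and cannot show a preference for convergent pairs. Under 10 kb, 21.8% of 1070 pairs were convergent (permutation p = 0.0094) and 53.8% tandem, with both motifs on 1 strand (permutation p = 0.0118), each with an adjusted p of 0.0708. In the second list of both pools, 51.6% of pairs were tandem over all distances, which leaves 24.2% convergent and 24.2% divergent (permutation tests, adjusted p = 0.0030 each, in effect a single test). Under 10 kb in that list, 54.3% were tandem (permutation test, adjusted p = 0.0030) and 22.6% convergent (0.0403). In the pool H list, 55.3% were tandem under 10 kb (permutation test, adjusted p = 0.0192). With the matrix learned outside soft-masked sequence, orientation changed with distance. Among 5732 pairs 100 kb to 1 Mb apart, 32.4% (31.2 to 33.6) were convergent and 18.9% (17.9 to 19.9) divergent, each against 25.0% permuted. Among 5406 pairs under 10 kb apart, the convergent share was 17.8% (16.8 to 18.9), and divergent pairs made up 27.4% and tandem pairs 54.8%. Each of these gave p = 0.0001, the smallest that 10000 permutations can give, and an adjusted p of 0.0002. The core with at most 1 mismatch gave 32.2% convergent pairs at 100 kb to 1 Mb and 19.3% under 10 kb; both of these matrices were applied after the planned result had been seen. With the planned matrix the convergent share at 100 kb to 1 Mb was 25.4% (permutation p = 0.567).

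**Figure D3:**
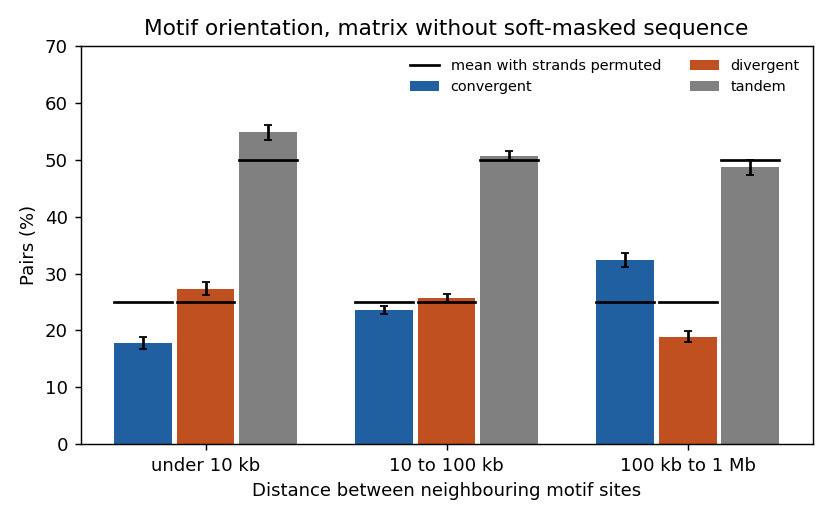
Convergent, divergent and tandem pairs of neighbouring motif sites (y axis, percent of pairs) in 3 distance classes (x axis), with the matrix learned outside soft-masked sequence, added after seeing the data. Bars carry 95% exact binomial intervals and black lines give the mean with strands permuted; convergent pairs rise from 17.8% under 10 kb to 32.4% at 100 kb to 1 Mb.

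Among gene groups, clustered protocadherins stood highest and odorant receptors lowest for promoter CTCF. Of all genes, 7580 of 21938 protein-coding genes, 34.6%, had a peak within 1 kb of a TSS. The clustered protocadherins, cell-surface adhesion proteins whose alternative promoters are known to bind CTCF, had one at 50 of 57 genes, 87.7% (76.3 to 94.9; Fisher exact test, adjusted p = 1.07e-15). The alpha cluster had 12 of 14, the beta cluster 19 of 22 and the gamma cluster 19 of 21. All 57 lie on chromosome 18 and are not independent genes. Olfactory and vomeronasal receptor genes, which are expressed in sensory neurons, had a peak at 12 of 1464, 0.820% (0.424 to 1.43, Fisher exact test, adjusted p = 3.00e-254), and also lie in clusters. Without a mappability track, a missing peak at these genes cannot be told apart from reads that could not be placed uniquely. These p-values are from two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 19 lists, and genes are not replicates.

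The other 17 lists did not pass the adjusted threshold. Cardiac transcription factors had promoter peaks at 13 of 23 genes (exact test, adjusted p = 0.172), CTCF and cohesin genes at 8 of 12 (0.141), energy metabolism genes of heart at 10 of 19 (0.344), sarcomere genes at 10 of 22 (0.638) and excitation and calcium genes at 9 of 22 (0.693). Fibroblast markers had them at 4 of 12 genes (1.0), endothelial markers at 3 of 12 (0.712), smooth muscle and pericyte markers at 2 of 10 (0.693) and immune markers at 1 of 12 (0.218). Of genes of other tissues, skeletal muscle markers had 5 of 12 (0.852), neuronal markers 3 of 16 (0.555) and hepatocyte markers 1 of 16 (0.103). Imprinted genes had 11 of 30 (0.896), housekeeping genes 8 of 18 (0.693), X-inactivation genes 4 of 10 (0.852), model loci of insulation 3 of 15 (0.555) and Hox genes 8 of 39 (0.245). With pool H alone, by the same exact test, the lists of CTCF and cohesin genes (9 of 12, adjusted p = 0.0161) and hepatocyte markers (0 of 16, adjusted p = 0.0152) passed as well. With promoters of 5 kb, hepatocyte markers passed at 3 of 16 (exact test, adjusted p = 0.0338). With 1 TSS per gene in place of any annotated TSS, only the protocadherin and receptor lists passed. Cardiac transcription factors then had promoter peaks at 11 of 23 genes, sarcomere genes at 6 of 22 and fibroblast markers at 2 of 12, against 27.1% of other genes.

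**Figure D4:**
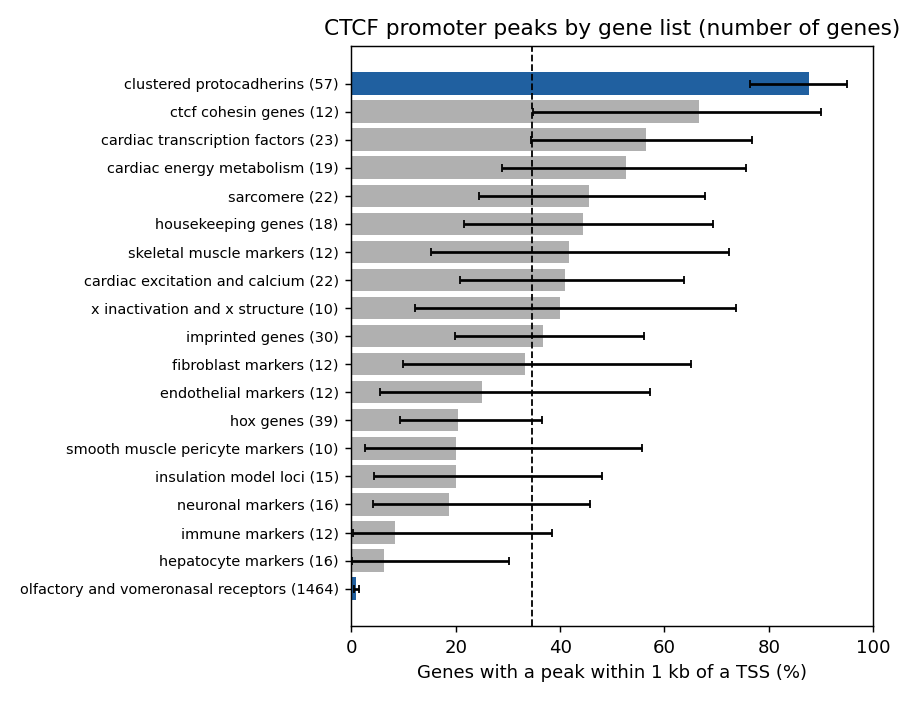
Share of genes with a conservative peak within 1 kb of a TSS (x axis, percent) for the 19 gene lists (y axis, with the number of genes). Bars in blue passed an adjusted p of 0.05, error bars are 95% exact binomial intervals and the dashed line is the 34.6% of all protein-coding genes.

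Promoter peaks of heart genes lay on both sides of 286, the median signal of all peaks. Of the genes with a promoter peak, those with one at or above it were 6 of 10 sarcomere genes, 5 of 13 cardiac transcription factors, 5 of 9 excitation and calcium genes and 6 of 10 energy metabolism genes. For scale, of the protein-coding genes outside the sarcomere list, 7570 had a promoter peak and 3913 had one at or above that median. The genes named here were taken for having the strongest promoter peaks of their lists, so their signals do not describe the lists. Actn2, the actin cross-linker of the Z-disc, had a peak on chromosome 13 from 12272900 to 12273361 with a signal of 717, which was 385 in the pool G list and 336 in the pool H list. Myl2, the ventricular regulatory myosin light chain, had one on chromosome 5 from 122104166 to 122104623 (signal 673), and Tpm1, an alpha-tropomyosin, one of the same signal 66 bp from a TSS. Ryr2, the calcium release channel of the sarcoplasmic reticulum, had a peak on chromosome 13 from 12106808 to 12107206 (625). Kcnj11, a subunit of the ATP-sensitive potassium channel, reached 593. Ckm, the muscle creatine kinase, had a peak on chromosome 7 from 19405276 to 19405801 (806), and Slc2a4, the insulin-responsive glucose transporter, reached 765. Among transcription factors, Tbx3 reached 622 and Srf 511. Actc1, Des, Hand1, Hand2, Casq2, Acadl and Acadm had no promoter peak in the list.

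Genes of other cell types also had promoter peaks on both sides of that median. Of the genes with a promoter peak, 4 of 4 fibroblast, 1 of 3 endothelial, 1 of 2 smooth muscle and pericyte, 0 of 1 immune, 4 of 5 skeletal muscle, 2 of 3 neuronal and 1 of 1 hepatocyte markers had one at or above it. Among the strongest of each list, above it were Col1a1 (771), Vwf (728), Myh11 (637), Mylpf (612), Rbfox3 (862) and Apob (767), which are known from fibroblasts, endothelium, smooth muscle, fast skeletal muscle, neurons and liver. Below it were C1qa of macrophages (230), Erg (169) and Eng (98.9) of endothelium, Smtn of smooth muscle (142) and Grin2b of neurons (88.6). Housekeeping genes Actb (792) and Rplp0 (780) had peaks above it. Of the cohesin group, Stag1 reached 743 and Pds5a 717. The Ctcf gene itself had a peak 73 bp from a TSS, on chromosome 8 from 105636553 to 105637196 (663).

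At H19 and Igf2, oppositely imprinted neighbours on chromosome 7, the peaks lay outside both genes. Upstream of H19, in the region known as its imprinting control region, 4 summits stood at -2.18, -2.67, -3.69 and -3.89 kb from the TSS, in intergenic sequence between 142580147 and 142582195, with signals of 201, 313, 346 and 222. Upstream of the nearest Igf2 TSS lay 3 intergenic summits at -4.43, -5.52 and -9.07 kb, of which the peak from 142672104 to 142672549 was the strongest (688). The cardiac myosin genes Myh6 and Myh7 on chromosome 14 each had 1 peak within 10 kb of a TSS and none in the gene body. The Myh6 peak, from 54939348 to 54939798, had a signal of 718 and lay beyond the 3' end of the gene, which spans 54941921 to 54966927. It was 4.93 kb downstream of the nearest annotated Myh6 TSS, one towards that end, and within 1 kb of another annotated TSS. The Myh7 peak was intergenic, at -7.06 kb (247). Nppa, which encodes atrial natriuretic peptide, had 2 peaks within 10 kb, of which the stronger (621) was 7.87 kb downstream. Nppb and Nkx2-5 had none within 10 kb. Gata4 had 5, the strongest (672) in an intron, and a promoter peak of 101. Myc had 5 summits, the strongest (721) upstream at -1962 bp from a TSS, on chromosome 15 from 61983174 to 61983700.

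The genes for the long non-coding RNAs Xist and Firre on X each held several peaks. Xist, which coats the inactive X, had 5 peaks within 10 kb of a TSS, the strongest (722) 973 bp upstream, from 103483967 to 103484443. Firre, from 50555744 to 50635321, held 27 summits in its 79.6 kb body, with signals from 178 to 588 and a median of 399.

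Of the 10 strongest peaks of the list, 4 lay at promoters, 3 between genes, 2 in introns and 1 in a 3' UTR. The highest signal, 889, was intergenic on chromosome 17 from 87044310 to 87044992, 19012 bp from the nearest protein-coding TSS, that of Cript. Next came a peak 60 bp from the Adam11 TSS on chromosome 11 (881), an intergenic peak 13.5 kb from Grm4 (880) and promoter peaks of Rinl (879) and Nipsnap2 (875). The remaining 5 had as nearest protein-coding TSS those of Arhgef19 (874, intergenic), Dnajc11 (874, 3' UTR), Slc6a5 (873, intron), Pick1 (872, promoter) and Oxgr1 (871, intron). In 9 of the 10 the core occurred with at most 1 mismatch, Adam11 being the exception.

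CTCF sites were sparsest on X. It held 1474 peaks, 8.62 per Mb (exact Poisson interval 8.18 to 9.07), below all 19 autosomes, which ranged from 15.8 per Mb on chromosome 3 to 32.9 per Mb on chromosome 11. The X density was 0.402 times that of the autosomes together. The median signal of X peaks, 290, lay within the autosomal range of 261 to 312. No peak of the list lay on Y in these female animals, which allows at most 0.0402 per Mb.

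**Figure D5:**
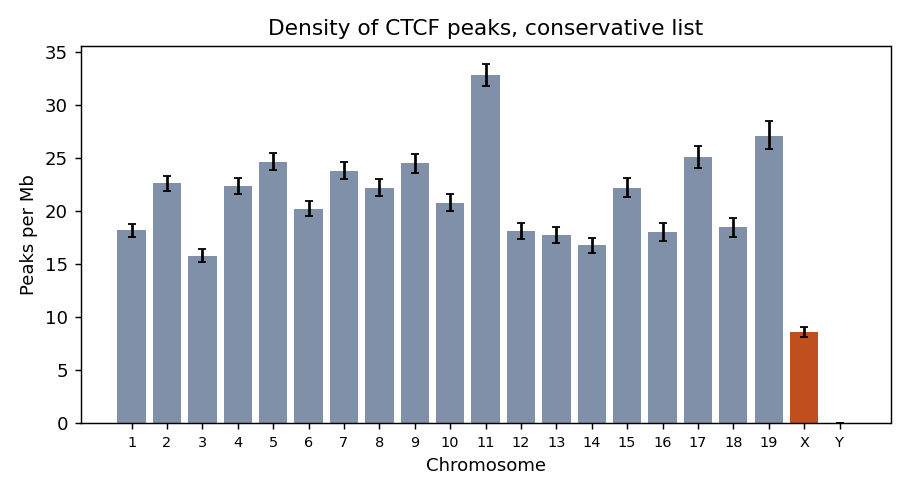
Peaks per Mb (y axis) of the conservative list on each chromosome (x axis), with exact Poisson 95% intervals; X is in orange. X has 8.62 peaks per Mb and the sparsest autosome, chromosome 3, 15.8.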

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

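The ranked lists hold peaks outside the chromosomes that were analysed. On the mitochondrial genome lay 18 peaks of the ranked list matched between pools, 20 of the second ranked list of both pools, 15 of the pool G list and 21 of the pool H list. On unplaced or unlocalized contigs lay 61, 72, 55 and 69 peaks of the same lists. All 8 counts exceed the limit of 3 that a count of 0 allows. No control library was at hand to set them against, and no explanation was tested.

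Some peaks of a ranked list with a scaled IDR of at least 540 are missing from the thresholded list made from that ranked list. There were 25 such peaks for the conservative list, 35 for the second list of both pools, 25 for pool G and 38 for pool H. Of the 25 for the conservative list, 15 lay on contigs and the others on chromosomes 1, 7, 16, 17 and 19. The strongest, on chromosome 19 from 61199332 to 61199816, had a signal of 703, and the median was 195. Of the 38 for pool H, 10 lay on the mitochondrial genome. No thresholded list held a peak outside the analysed chromosomes, so contig and mitochondrial peaks were absent as a group. All those of the conservative list on chromosome 7 had a scaled IDR of exactly 540, and each other list also lacked some peaks at 540. This whole number can also stand for an IDR just above 0.05, so such peaks may not have passed the threshold.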

How the results depend on the processing

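The other matrices of the motif and their orientation, the receptor-free background and the first prefix match were chosen after the results were seen; the other alternatives were planned. Of the values behind the main comparisons, 46 kept their direction and side of the threshold or stayed within their error, 10 moved further, 3 gained a call and 1 reversed. Of those for single features and gene lists 175 kept them, 2 lost their call, both for 5' UTRs (pool G list and stronger peaks), 3 gained one and 2 reversed. The promoter excess, the depletion of soft-masked sequence, the lower signal of promoter peaks and the excess of the motif over paired windows kept their direction under each alternative run. Their sizes changed: with promoters of 5 kb the promoter excess was 1.87-fold and the promoter signal difference -0.0924. Among peaks at or above the median signal, 12.6% of summits were soft-masked. The motif share changed as well. With the planned matrix it was 2.56% at the stricter score threshold, 31.6% with windows of 50 bp either side and 6.57% with 250 bp. Without a learned matrix, the seed at up to 1 mismatch gave 65.7%. The 9 versions added after seeing the data gave 21.3% (core alone, with 0, 1 or 3 rounds), 23.3% and 25.6% (4 flanking bases, 1 and 0 rounds), 28.0% (training on the stronger peaks), 41.1% (training on the top 10%), 32.5% (exact seed) and 46.9% (outside soft-masked sequence).

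The list has 27155 peaks with a signal at or above the median. With 50% reciprocal overlap, the share of conservative peaks found was 96.6% in the second list of both pools, 85.1% in the pool G list and 78.8% in the pool H list; with summits within 100 bp it was 96.5%, 90.5% and 87.9%. The correlation of pool signals was 0.959 past the threshold, which selects peaks for that agreement, and the X density was 9.69 per Mb in the second list of both pools. The convergent share over all distances was, by permutation test, 24.2% in that list (p = 0.001), 24.5% with the matrix outside soft-masked sequence (p = 0.0007) and 24.1% with the seed (p = 0.0001), below the permuted share. At the stricter score threshold it was 26.0%, above the permuted share (permutation p = 0.123). Convergent and divergent pairs alternate along a chromosome, so these shares only mirror the share of tandem pairs. They show no depletion of convergent pairs relative to divergent ones. The intron share turned to a depletion at 39.1% among the stronger peaks and 27.1% with 5 kb promoters. Except where the alternative itself narrows the peaks used, the cause was not tested.

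The lists of single pools leave out a replicate each. They gave 50577 to 54658 peaks, promoter shares of 20.4 to 20.9%, motif shares of 15.2 to 15.3%, convergent shares of 24.6% in both, X densities of 8.19 to 8.61 per Mb, promoter differences of -0.27 to -0.26, soft-masked shares of 20.9 to 21.4% and 2 to 4 gene lists past the threshold, against 2. No paired analysis was possible because the lists hold no value per library, and technical numbers 1 and 2 mark different libraries in the 2 pools. Unknown depth limits the comparison of weak peaks.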

Other observations

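Firre was the most densely occupied of 6024 genes of at least 50 kb, with 339 summits per Mb of gene body. The next was Wdtc1 on chromosome 4 with 197, and the fifth was 4933407K13Rik on X with 173. Within Firre, 6 of the 27 peaks had the core with at most 1 mismatch, 0 had the motif of the matrix learned outside soft-masked sequence, and 2 summits were soft-masked. The protocadherin promoter peaks were also poor in the core, with 5 of 50 having it within 1 mismatch. Their median signal was 245 in the alpha, 251 in the beta and 382 in the gamma cluster. Protocadherins without a promoter peak were Pcdha1, Pcdhac2, Pcdhb1, Pcdhb9, Pcdhb22, Pcdhgc4 and Pcdhgc5. These values were chosen after seeing the data.

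Copies of the core followed by a G were occupied more often. Outside soft-masked sequence and leaving out CCAGAAGAGGGC, 81.0% of 3913 such copies had a peak (79.7 to 82.2), against 44.4% of 13311 others (43.5 to 45.2). The share was higher with the G for each of the 31 words, with a Mantel-Haenszel odds ratio of 5.58. The G makes a CpG with the last base of the core. That position is also part of the motif: in the matrix learned outside soft-masked sequence it held A at 0.476, G at 0.474, C at 0.0143 and T at 0.0355. The other copies join A, C and T there and were not separated, so the comparison does not tell a CpG from a preferred base. Of the same unmasked copies, those of the 4 words with a CpG inside, which all begin with CCACGAG, were occupied at 39.1% of 494 (34.7 to 43.5), against 53.1% of 16730 others (52.3 to 53.9). Word by word these 4 had 31.5 to 52.3%, and the 4 words that begin with CCAGGAG, with a G at the same position and no CpG, 7.11 to 22.7%. These groups of words also differ in the base before that G, which is C in the words with a CpG and G in the others. Among words without a CpG inside that differ only in this base, unmasked copies with C were occupied more often in every pair. The comparison therefore does not tell a CpG from that base, and no explanation was tested.

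The tests in the paragraphs that follow were written down before their results were seen; the first pattern and its word had been noticed beforehand, and the comparison word by word was added after seeing the data. Peaks at the word CCAGAAGAGGGC were weaker than those at other words, with a difference of medians of -1.73 on the log2 scale (bootstrap interval -1.77 to -1.68). One technical candidate is loss of reads in repeats. Among the other words, soft-masked sites differed from unmasked ones by -1.28 (-1.37 to -1.18), which goes with it, and 13 of 14 words with at least 20 sites of both kinds were lower, from -1.58 to 0.03. The word itself may also matter: within soft-masked sequence it differed from the other words by -0.57 (-0.67 to -0.48), and at its 21 unmasked occupied copies by -0.76 (-1.70 to -0.28). Both stay open, as does the sequence around the core, and no biological explanation was tested.

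Between the pools, 10350 peaks passed the threshold in 1 pool only. Of these, 98.6% overlapped a peak of the other pool's ranked list (98.4 to 98.9), as a depth or threshold effect would give. Sites without the motif as a separate class could not be decided, as the core within 1 mismatch was rarer in peaks of 1 pool only than in shared peaks by 10.1 percentage points (9.08 to 11.1), an interval that includes the bound of 10 set beforehand. Peaks of 1 pool only were also weaker, with a median signal of 54.6 against 174 in the pool G list and 42.2 against 145 in the pool H list. The core share rose with signal in the conservative list, from 46.4% in the weakest decile to 81.6% in the strongest. The peaks were not matched for signal, so the difference cannot separate such a class from weak peaks. A difference between the pools of animals stays open and was not tested.

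The low density on X may have several sources. Fewer copies of the core cannot be the whole of it: X had 17.8 exact copies per Mb, against 20.8 to 46.8 on autosomes, yet 16.5% of its copies were occupied (15.2 to 17.9), below the autosomal range of 21.4 to 27.6%. In unmasked sequence 45.1% of X copies were occupied (41.0 to 49.2), inside the autosomal range of 42.2 to 58.1% though below 18 of the 19 autosomes, which is consistent with a part played by repeat-rich sequence. Unmasked copies were also scarcer on X, at 3.46 per Mb against 4.70 to 9.19. X inactivation was not tested, since the lists do not separate the parental alleles.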
